A study of Mus musculus with 4 samples.

How the data were processed

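RNA expression was measured on 4 Affymetrix arrays from the mouse thymic lymphoma line T29, which the series' design text calls Ikaros-deficient. All 4 samples carried the same retroviral construct, MigR1-MLER, an inducible form of dominant-negative Mastermind. Mastermind is the co-activator that Notch needs to switch on its target genes. Cells were kept for 24 h with ethanol (2 samples) or with 100 nM 4OHT (2 samples), per the labels' protocols. 4OHT is the tamoxifen metabolite that binds oestrogen receptor fusions. No sample without the construct was analysed here. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

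The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, equalises the distribution of probe signals over the arrays and summarises the probes of each set. Its version and any further filter are not given in the sources used here. The log2 scale was taken from the values, which lay between 2.25 and 14.6, with array medians from 5.12 to 5.14. RMA gives no detection call and no read depth. The number of arrays therefore limits the precision, and folds against a level near background can be understated.

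The value table held 45101 probe sets, of which 64 were controls. The platform annotation named exactly 1 gene for 34945 non-control probe sets and several for 932, and 9211 probe sets, controls included, were unnamed here. Symbols were checked through the gene number against a RefSeq gene table of assembly GRCm38.p6. None changed, and 204 probe sets had no match and kept their symbol. Each of the 18193 genes was represented by the probe set with the highest mean over all 4 arrays. Genes with a mean under the 40th percentile of the named probe sets, a log2 value of 4.81, were not tested. That left 11581 genes and removed 6612. The files carry no coordinates; the gene table served only for names and for the order of neighbouring genes, and its coordinates are not printed.

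The 4OHT and ethanol groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend, all 4 arrays, no block), with Benjamini-Hochberg adjustment over the genes tested and a call at an adjusted p under 0.05. Means are given with the SD over 2 arrays, and log2 changes, 4OHT minus ethanol, with limma's standard error (SE). Adjusted p-values of single genes come from this fit unless another fit is named. A set of 21 gene lists was fixed before the data were examined, from textbook knowledge, and 363 of its 390 entries had a probe set naming 1 gene. The 18 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list moved, on balance, one way.

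The genes named were also set by a rule before the data were examined. It took the 10 largest called rises and the 10 largest called falls, leaving out clone and predicted-gene names and genes whose groups overlapped. It added up to 4 members of each list, called ones first, and 12 genes named in advance. Genes named outside this rule are marked as chosen after their values were seen.

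The fit was tested on simulated data of 11581 genes with 200 changed genes, in 20 runs of 2 arrays against 2. It recovered 6% of changes of 0.5 on the log2 scale, 82.7% of changes of 1 and 98.1% of changes of 2, and 5.36% of its calls were false. The simulated noise was independent between genes and arrays, and fewer genes were changed than the 865 called in the data. These shares therefore need not hold for the data. A simulated list shifted down by 0.5 passed camera with the preset correlation. With the estimated correlation the same list had an adjusted p of 0.0729, in a design with 2 residual degrees of freedom.

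The alternatives tried were no filter, a filter at the 60th percentile, quantile normalization or median centring on top of the deposited values, the replicate number as a block, each array left out in turn, the mean of a gene's probe sets, all probe sets, an intensity trend with or without a robust prior, other thresholds, and camera on ranks. A fit without probe sets marked for possible cross-hybridisation (_x_at and _s_at) was added after seeing the data.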

Results

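Expression of 11581 genes was compared between 2 ethanol-treated and 2 4OHT-treated samples of T29 cells carrying inducible dominant-negative Mastermind. The comparison asks which genes in this Ikaros-deficient mouse T-cell lymphoma line respond when Notch-dependent transcription is blocked for 24 h. Arrays correlated more closely within a group than between groups. Across tested genes, Pearson's r was 0.995 for the 2 ethanol arrays and 0.995 for the 2 4OHT arrays, against 0.983 to 0.987 between groups. The first principal component, with 69.4% of the variance, separated the groups. As a measure of RNA quality, the 3′ minus 5′ log2 difference of the Actb control probe sets was 0.40 and 0.49 on the ethanol arrays and 0.43 and 0.45 on the 4OHT arrays. That of the 18S ribosomal RNA control moved with the groups, at 0.05 and 0.32 with ethanol and 0.90 and 0.82 with 4OHT. Differences between groups in the means were -0.013 for Gapdh, 0.13 for pyruvate carboxylase and -0.060 for the transferrin receptor. Ethanol replicate 1 stood apart in the level of the 18S 5′ probe set, at 8.02 against 6.78, 6.35 and 6.74 on the other arrays, and of the transferrin receptor 5′ probe set, at 8.27 against 6.99, 7.33 and 7.14.

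With 4OHT, 452 genes were higher and 413 lower, and these 865 genes were 7.47% of those tested. The median fold was 1.62 among the higher genes and 1.52 among the lower ones. At least 2-fold changes were found for 91 higher and 50 lower genes. With clone and predicted-gene names left out, the strongest falls were in Exoc3l4 and Dtx1, and the strongest rise was in Slc6a20a, an amino acid transporter gene. The groups did not overlap for 56.9% of tested genes, where chance gives 33.3% with 2 arrays against 2. A fit that leaves out 1 array has 1 residual degree of freedom, so a call lost there does not by itself weigh against a gene. The calls were made with limma at an adjusted p under 0.05. They rest on all 4 arrays: leaving out 1 array lowered the counts of higher and lower genes to 94 and 55 (without ethanol replicate 1), 125 and 66 (ethanol replicate 2), 9 and 12 (4OHT replicate 1) or 39 and 36 (4OHT replicate 2). Of the 63 named genes that were called, all kept their direction in these fits and 13 kept the call in every one.

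**Figure D1:**
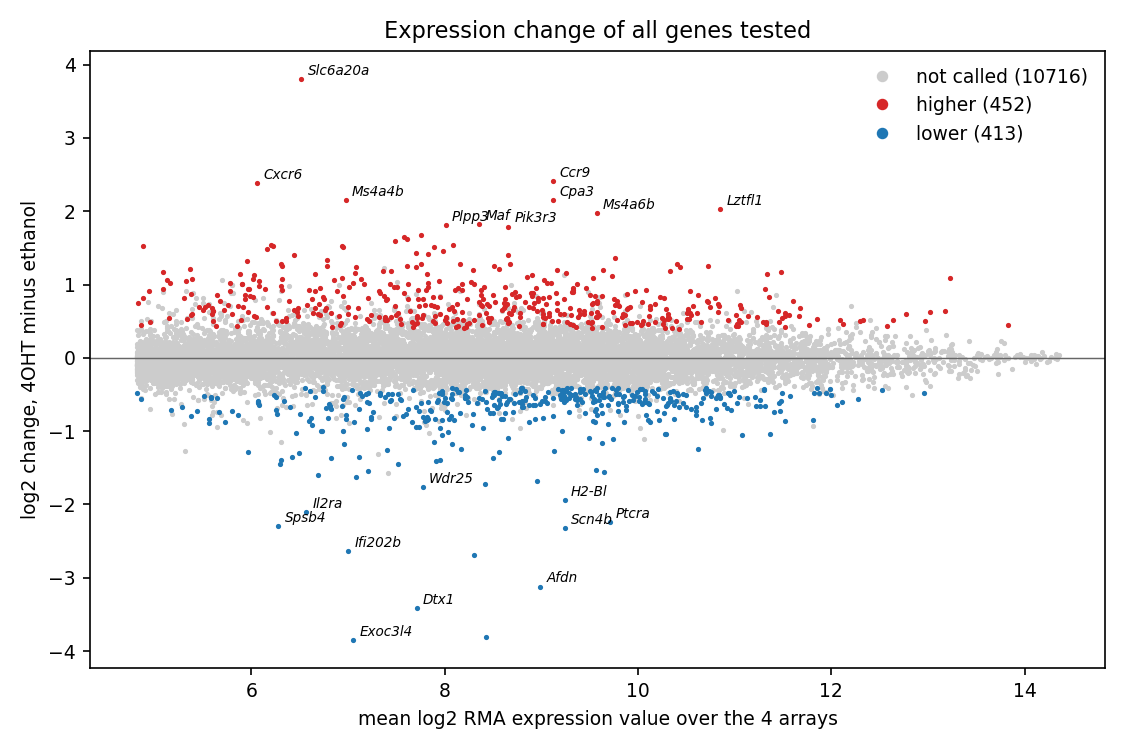
Log2 change (4OHT minus ethanol, vertical axis) of each of the 11581 tested genes against its mean log2 RMA value over the 4 arrays (horizontal axis), with 452 genes called higher in red, 413 called lower in blue and the rest in grey. The named points are the 10 largest called rises and the 10 largest called falls with a gene symbol that is not a clone or predicted-gene name.

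Established Notch target genes were among those that fell. Of 19 tested members of the T-cell Notch target list, 9 were lower with 4OHT, none was higher, and 10 did not pass. Dtx1, a ubiquitin ligase gene and standard Notch readout, fell 10.6-fold, from 9.42 ± 0.01 to 6.01 ± 0.00 (mean log2 value ± SD, n = 2 each; log2 change -3.41 ± 0.08 SE, limma adjusted p = 0.000506). Ptcra, which encodes the pre-T-cell receptor alpha chain, fell 4.71-fold (log2 change -2.23 ± 0.11, adjusted p = 0.00221). Il2ra, the interleukin-2 receptor alpha chain, fell 4.31-fold (-2.11 ± 0.25, adjusted p = 0.0171). The repressor gene Hes1 fell 2.62-fold (-1.39 ± 0.12, adjusted p = 0.00945) and Nrarp, a feedback inhibitor of Notch, 2.72-fold (-1.44 ± 0.20, adjusted p = 0.0229). The receptor genes Notch3 and Notch1 were 3.19-fold and 1.82-fold lower (adjusted p = 0.018 and 0.0259). Myc, the growth-promoting transcription factor, fell 1.67-fold, from 11.78 ± 0.22 to 11.04 ± 0.11 (n = 2 each, adjusted p = 0.0358). Trib2 (log2 change -0.57, adjusted p = 0.0296) completed the 9 falling members and was named after its value was seen, as was Gata3 (0.70, adjusted p = 0.0659). Heyl was at 5.31 with ethanol and 4.98 with 4OHT, close to the testing floor of 4.81, and did not pass (adjusted p = 0.0798).

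The list as a whole shifted down, with a median log2 change of -0.57 (camera adjusted p = 5.41e-05). With an estimated correlation its adjusted p was 0.287, and no list passed that test. The correlation estimated for this list was 0.0096, against the preset 0.01, so a larger correlation was not the reason. In this design with 2 residual degrees of freedom, the test also missed a simulated list that had been shifted (adjusted p = 0.0729). A miss there therefore cannot decide whether the Notch list shifted. Fry gave an adjusted p of 0.0262. Adjusted over the list alone, 11 members were lower and 1 higher. Dtx1 and Ptcra kept their calls whichever array was left out, while Myc lost its call in each of these fits (adjusted p from 0.0591 to 0.167). The number of lower members was 6 without either ethanol array, 2 without 4OHT replicate 1 and 3 without 4OHT replicate 2. None of 26 tested genes for Notch receptors, ligands and machinery passed in limma, nor when adjusted over the list alone (4 higher and 2 lower at an unadjusted p under 0.05), with a median change of 0.02 and a camera adjusted p of 0.402. Their nearest members were Mfng, a fringe glycosyltransferase (-0.53 ± 0.13, adjusted p = 0.0679), and Ep300, a histone acetyltransferase (0.42 ± 0.10, adjusted p = 0.073). Fry's mixed test, which counts changes in either direction, passed for this list (adjusted p = 0.00458), as it did for most lists. Maml1 was at 8.74 ± 0.12 with ethanol and 8.94 ± 0.09 with 4OHT (adjusted p = 0.285). Both groups carried the construct and the place of the probes in it is not known here, so this value does not check its expression. Ikzf1, which encodes Ikaros, was at 10.03 ± 0.03 with ethanol and 1.38-fold higher with 4OHT (adjusted p = 0.0361); where its probe set lies relative to the mutation of the line is not given in the sources used here.

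**Figure D2:**
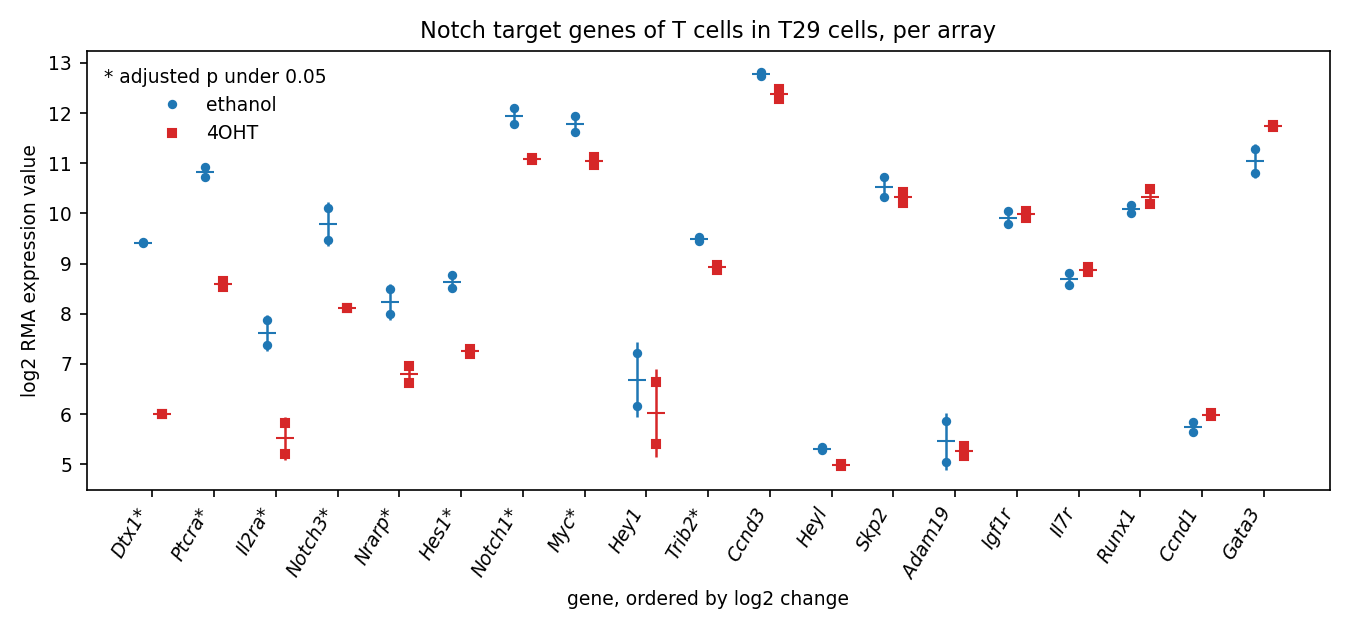
Log2 RMA expression value (vertical axis) of the 19 tested Notch target genes on each of the 4 arrays (blue circles ethanol, red squares 4OHT), with the mean as a horizontal tick and the SD over 2 arrays as a vertical bar; asterisks mark an adjusted p under 0.05. The 9 marked genes lie lower in both 4OHT arrays than in both ethanol arrays, with Dtx1 moving from 9.42 to 6.01.

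Growth genes were also among those that fell. All 32 tested members of the MYC-driven growth and ribosome biogenesis list had a change below 0, and 22 of them passed the test. Srm, spermidine synthase, fell 2.06-fold (-1.04 ± 0.09, adjusted p = 0.01), and Nop58, a core box C/D snoRNP protein gene, 1.80-fold (-0.85 ± 0.11, adjusted p = 0.0217). Polr1b, an RNA polymerase I subunit gene, fell 1.79-fold (adjusted p = 0.0279) and Rrp9, of the U3 snoRNP, 1.67-fold (adjusted p = 0.0164). The list median was -0.53 (camera adjusted p = 1.36e-16; adjusted p = 0.182 with an estimated correlation; fry adjusted p = 0.00487). Adjusted over the list alone, 29 members were lower. The single-gene calls fell to 2 without either ethanol array and to 0 without either 4OHT array, while the camera call of the list held in each of these fits.

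Of 20 tested cholesterol synthesis and uptake genes, 6 fell and none rose, 11 fell when adjusted over the list alone, and 19 had a change below 0. Lss, lanosterol synthase, fell 2.00-fold (SE 0.21 on the log2 scale, adjusted p = 0.0489), Cyp51, lanosterol demethylase, 1.54-fold (adjusted p = 0.0363), Msmo1, a sterol methyl oxidase gene, 1.53-fold (adjusted p = 0.0306) and Fdft1, squalene synthase, 1.53-fold (adjusted p = 0.0468). The list median was -0.43 (camera adjusted p = 5.2e-06; adjusted p = 0.566 with an estimated correlation; fry adjusted p = 0.138). No single member passed when any 1 array was left out. Glycolysis genes had a median of -0.23, with none of 15 passing in limma or when adjusted over the list alone (2 at an unadjusted p under 0.05) and a camera adjusted p of 0.0656 (adjusted p = 0.694 with an estimated correlation). Camera called that list lower without ethanol replicate 1 and without 4OHT replicate 2. It also did so with the mean of each gene's probe sets (adjusted p = 0.0426), on ranks (adjusted p = 0.0435) and with the replicate block (adjusted p = 0.0013). Slc2a1, the main glucose transporter gene, was at 10.50 ± 0.23 with ethanol and 9.55 ± 0.79 with 4OHT (n = 2 each, adjusted p = 0.178).

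No gene of the S phase or the G2 and mitosis list passed the test. None of 22 S phase and DNA replication genes passed in limma or when adjusted over the list alone (1 higher and 3 lower at an unadjusted p under 0.05). Their median was -0.08 (camera adjusted p = 0.312), and fry, which does not set a list against other genes, placed it lower (adjusted p = 0.0286). The replication regulator E2f1 was at a log2 change of -0.34 (adjusted p = 0.101). None of 20 G2 and mitosis genes passed in limma or when adjusted over the list alone (3 at an unadjusted p under 0.05). Camera with the preset correlation nonetheless placed the G2 and mitosis list higher, with a median of 0.14 (adjusted p = 0.0134). Camera with an estimated correlation (adjusted p = 0.599) and fry (adjusted p = 0.315) did not call it. The correlation estimated for this list was 0.657, far above the preset 0.01, so the preset p can be too small. Ccnb2, a mitotic cyclin gene, was at 11.77 ± 0.01 with ethanol and 12.16 ± 0.05 with 4OHT (adjusted p = 0.0539), and the proliferation marker Mki67 at 12.25 ± 0.12 and 12.57 ± 0.08 (adjusted p = 0.13). The set call was lost without ethanol replicate 1 (adjusted p = 0.0605) and without 4OHT replicate 2 (adjusted p = 0.221).

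Of 15 tested genes that mark stages of T-cell development, 6 rose, none fell, and 14 had a change above 0; adjusted over the list alone, 9 were higher and 1 lower. Ccr9, a thymocyte chemokine receptor gene, rose 5.32-fold, from 7.92 ± 0.02 to 10.33 ± 0.15 (n = 2 each; 2.41 ± 0.10, adjusted p = 0.00178). Cd27, a TNF receptor family member, rose 1.87-fold (adjusted p = 0.0121) and the co-receptor gene Cd8a 1.78-fold (adjusted p = 0.0347). The adhesion receptor gene Cd44 rose 2.31-fold (adjusted p = 0.0119), from 4.76, which is below the testing floor, to 5.97. The list median was 0.49 (camera adjusted p = 7.9e-07; adjusted p = 0.287 with an estimated correlation; fry adjusted p = 0.0286). The number of higher members was 2, 4, 1 and 1 without ethanol replicate 1, ethanol replicate 2, 4OHT replicate 1 and 4OHT replicate 2.

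T-cell receptor signalling genes moved in both directions. Of 14 tested, 5 were higher and 1 lower (7 and 1 adjusted over the list alone). Prkcq, protein kinase C theta, rose 2.23-fold (1.15 ± 0.10, adjusted p = 0.01), Cd247, the zeta chain, by 0.68 on the log2 scale (adjusted p = 0.0347), the co-stimulatory receptor gene Cd28 1.55-fold (adjusted p = 0.0446) and Ptprc, which encodes CD45, 1.51-fold (adjusted p = 0.0295). The falling member was Cd3g (-0.57, adjusted p = 0.0356), named after its value was seen. The list median was 0.31 (camera adjusted p = 0.00969; adjusted p = 0.566 with an estimated correlation; fry adjusted p = 0.108). At most 1 member passed when 1 array was left out.

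Among 20 T-lineage transcription factor genes, 5 were higher and 2 lower (6 and 2 adjusted over the list alone). Sox13 rose 2.66-fold (1.41 ± 0.19, adjusted p = 0.0218), Ikzf2, which encodes Helios, 1.78-fold (adjusted p = 0.0173) and Id3, an inhibitor of E proteins, 1.66-fold (adjusted p = 0.0469). Lef1, a TCF family factor gene, fell 1.66-fold (-0.73 ± 0.11, adjusted p = 0.0268). The list median was 0.20 (camera adjusted p = 0.0312; adjusted p = 0.427 with an estimated correlation; fry adjusted p = 0.0984), and the set call was lost with no filter on dim genes (adjusted p = 0.0873) and without 4OHT replicate 2 (adjusted p = 0.0514). Of 14 FOXO target and quiescence genes, 5 rose and none fell (7 and 0 adjusted over the list alone). Txnip, a thioredoxin inhibitor gene, rose 2.57-fold (1.36 ± 0.21, adjusted p = 0.0269), the repressor gene Bcl6 1.78-fold (adjusted p = 0.0266), Ccng2, an atypical cyclin gene, 1.56-fold (adjusted p = 0.0242) and Foxo3 itself by 0.59 on the log2 scale (adjusted p = 0.0267). That list had a median of 0.46 (camera adjusted p = 3.98e-05; adjusted p = 0.287 with an estimated correlation; fry adjusted p = 0.0286). Leaving out 1 array left at most 2 called members of the transcription factor list and at most 1 of the FOXO list.

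Stress, survival and interferon genes changed in small numbers. In the p53 list, 2 of 14 rose and 1 fell (4 and 2 adjusted over the list alone). Trp53inp1 rose 2.25-fold (adjusted p = 0.0123) and Gadd45a, a growth arrest gene, 1.96-fold (adjusted p = 0.0159), while the nuclease gene Aen fell 1.40-fold (adjusted p = 0.036). In the BCL2 family, Bmf, a BH3-only gene, rose 2.01-fold (adjusted p = 0.0333) and was the 1 member of 10 to pass, also adjusted over the list alone; another of its probe sets moved the other way, by -0.14. In the interferon list, Mx1 rose 2.51-fold (adjusted p = 0.0124) and Usp18 2.39-fold (adjusted p = 0.0109), 2 of 13 in all and 4 adjusted over the list alone. In the ER stress and amino acid list, Slc7a11, the cystine transporter gene, rose 2.02-fold (adjusted p = 0.0151) and the ER chaperone gene Sdf2l1 fell 1.48-fold (adjusted p = 0.0386), of 19 tested, and 1 was higher and 1 lower adjusted over the list alone. Camera put the p53 list (adjusted p = 0.0338) and the interferon list (adjusted p = 0.0134) higher, the ER stress list lower (adjusted p = 0.0338), and the BCL2 family did not pass (adjusted p = 0.138), except without 4OHT replicate 2 (adjusted p = 0.0365). With an estimated correlation the adjusted p-values were 0.532 for p53, 0.566 for interferon and 0.584 for ER stress, and with fry they were 0.0984, 0.138 and 0.545. Each of these 3 set calls was lost without 4OHT replicate 1, at an adjusted p of 0.0864 for p53, 0.0864 for interferon and 0.368 for ER stress, and those of interferon (adjusted p = 0.0565) and ER stress (adjusted p = 0.0546) also without ethanol replicate 2. The p53 call was also lost with a filter at the 60th percentile (adjusted p = 0.0682).

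The oestrogen receptor target list was included because 4OHT binds that receptor. Of 10 tested members, 3 rose: Greb1 1.76-fold (0.81 ± 0.12, adjusted p = 0.0266), Esr1, the receptor gene itself, 1.64-fold (adjusted p = 0.0311) and Ctsd, cathepsin D, 1.38-fold (adjusted p = 0.0359). Adjusted over the list alone, 4 were higher. Without ethanol replicate 2 only Greb1 kept its call (adjusted p = 0.0478), and no member was called without any other array. The list median was 0.10 and camera did not call it (adjusted p = 0.138), except with a filter at the 60th percentile (adjusted p = 0.0173). Whether the Esr1 probe set also reads an oestrogen receptor part of the construct is not known here.

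Markers of other cell types were mostly dim. Of the lineage lists, only those of B-cell and of stromal, epithelial and endothelial markers were tested as sets. Neither passed camera (adjusted p = 0.766 and 0.856). Fry's mixed test, which counts changes in either direction, passed for both (adjusted p = 0.0309 and 0.0206). Of the 18 tested lists, only those of G2 and mitosis (adjusted p = 0.0854) and of glycolysis (adjusted p = 0.59) missed it. A pass therefore does not set the B-cell and stromal lists apart. Median, mean and test differed in sign: the B-cell median was -0.10, the mean 0.01 and the camera direction down, and the stromal median was -0.07, the mean 0.07, the camera direction down and the fry direction up. Single members that rose were Ighm (1.49-fold, adjusted p = 0.0305), for which another probe set moved by -0.12, Pecam1 (1.90-fold, adjusted p = 0.0165), and the granzyme gene Gzma (2.13-fold, from 12.68 to 13.77, adjusted p = 0.0121), 1 of 3 tested NK-cell and cytotoxic markers. Adjusted over the list alone, 1 of 5 B-cell markers and 1 NK-cell marker were higher, and 1 of 5 stromal markers was higher and 1 lower. Among the other B-cell markers, Cd22 was at 5.11 with ethanol and 4.89 with 4OHT and Pax5 at 5.39 and 5.29. None of 4 myeloid markers passed in limma (1 at an unadjusted p under 0.05, which was lower when adjusted over the list alone), with Cd14 at 6.36 and 5.99 and Spi1 at 5.94 and 5.66. None of 3 erythroid markers passed in limma (2 at an unadjusted p under 0.05, 1 higher and 1 lower when adjusted over the list alone). Lists of fewer than 5 tested members were not tested as sets.

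Most of the genes with the largest changes lay outside these lists. Exoc3l4 fell 14.4-fold, from 8.98 ± 0.14 to 5.13 ± 0.17 (n = 2 each; -3.84 ± 0.12, adjusted p = 0.000634). Afdn, the junction protein afadin, fell 8.68-fold (adjusted p = 0.00136), with a second probe set at -0.51. Ifi202b, of an interferon-inducible family with near-identical members, fell 6.23-fold (adjusted p = 0.0151). Scn4b, a sodium channel beta subunit gene, fell 5.02-fold (adjusted p = 0.00197), Spsb4, a SOCS box gene, 4.90-fold (adjusted p = 0.0121), the class I MHC gene H2-Bl 3.84-fold (adjusted p = 0.00221) and Wdr25 3.38-fold (adjusted p = 0.00945). Related class I genes share sequence, so the H2-Bl signal is uncertain.

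Slc6a20a rose from 4.61 ± 0.08, below the testing floor, to 8.42 ± 0.14 (n = 2 each), a log2 change of 3.81 (SE 0.11, adjusted p = 0.000634). The chemokine receptor gene Cxcr6 rose 5.20-fold (adjusted p = 0.00788), Cpa3, a carboxypeptidase gene of mast cells, 4.43-fold (adjusted p = 0.00428) and Lztfl1, a ciliary trafficking gene, 4.07-fold (adjusted p = 0.0107). The MS4A family genes Ms4a4b and Ms4a6b, members of a family of related sequence, rose 4.45-fold (adjusted p = 0.00893) and 3.94-fold (adjusted p = 0.00178). Maf, a transcription factor gene, rose 3.54-fold (adjusted p = 0.00668), with 4 of its 5 probe sets higher. Plpp3, a lipid phosphatase gene, rose by 1.81 on the log2 scale (adjusted p = 0.0116) and Pik3r3, a PI3-kinase regulatory subunit gene, 3.46-fold (adjusted p = 0.0165). Of 451 called genes with more than 1 tested probe set, all probe sets moved the same way in 417. Of the 20 genes named for the size of their change, which leave out clone and predicted-gene names, Cpa3, Ifi202b, Il2ra, Plpp3, Lztfl1, Ms4a4b and Pik3r3 lost their call in at least 1 of the 4 fits that leave out an array, at adjusted p-values up to 0.0872.

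**Figure D3:**
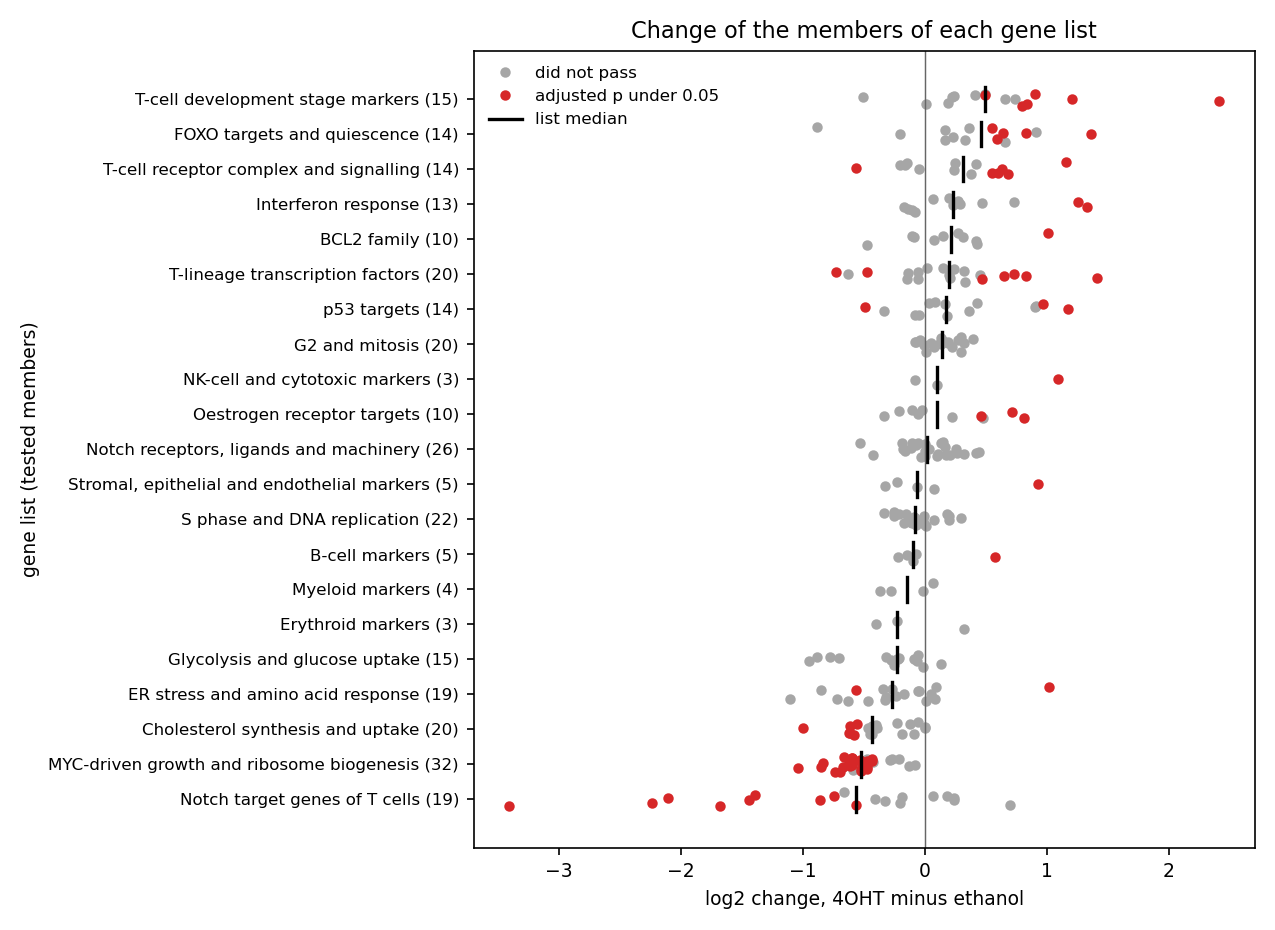
Log2 change (4OHT minus ethanol, horizontal axis) of every tested member of the 21 gene lists (vertical axis, tested members in parentheses), ordered by list median; red points passed at an adjusted p under 0.05, grey points did not, and black bars are list medians. Notch targets (median -0.57), MYC-driven growth (-0.53) and cholesterol genes (-0.43) lie lowest, and T-cell development markers (0.49) and FOXO targets (0.46) highest.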

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

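Both tests of this part were set out before their results were seen. A signal also appeared in probe sets that the gene comparison did not use. Of 2819 unnamed probe sets tested in a limma fit of all 24375 probe sets, 162 were called higher with 4OHT and 8 lower, so that 95.3% of the calls were higher (95% exact binomial interval 90.9 to 97.9). The interval treats probe sets as independent, though all were read on the same 4 arrays. It does not measure the spread between samples. Among probe sets listed in the annotation, 418 were higher and 275 lower, which is 60.3%. Unnamed probe sets were dimmer, with a median log2 level of 6.04 against 7.81. Lower signal alone is argued against, since 1000 draws of named probe sets matched on signal gave between 50.6% and 81.5% higher calls, against 95.3% (95.29) in the unnamed ones. Quantile normalization on top left 94.6% higher (106 higher and 6 lower) against 55.5% in named probe sets. RMA already equalises the arrays, so this test could not undo a distortion made there, and the deposited normalization stays open. The 18S control's 3′ minus 5′ difference was 0.68 higher with 4OHT. Those of the other controls moved less, by -0.005 for Actb, -0.013 for Gapdh, 0.13 for pyruvate carboxylase and -0.060 for the transferrin receptor. A difference in RNA quality was not tested as a cause. The levels of some control probe sets also differed between groups. With 4OHT, BioDn-5 changed by 0.16, CreX-5 by 0.17 and ThrX-5, which lay under the testing floor, by -0.21. BioB-5 and BioC-5 changed by only -0.009 and 0.018. Whether these differences bear on the normalization was not tested. What the unnamed probe sets measure is not known here: transcripts from introns, antisense RNA and long non-coding RNA stay open, and no biological explanation was tested.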

How the results depend on the processing

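Neither normalization on top of the deposited values changed the counts of called genes by over 1.5 times. The arrays were already nearly equal, with medians from 5.12 to 5.14, which left these steps little to change. They therefore cannot test the deposited normalization. The counts of higher and lower genes moved with how the spread was estimated. The labels number the replicates, but with 2 pairs and no statement of a shared day the main fit took no pairing. The values did differ by number. Replicate 2 minus replicate 1 correlated at 0.343 across genes between the groups, and the second principal component (20.7% of the variance) separated the numbers. The fit without a block keeps this difference in its spread, so it can call too few genes. With the replicate block, 1104 genes were higher and 1031 lower, including all 865 of the fit without it. The glycolysis list then passed camera (adjusted p = 0.0013), and no other camera call changed. The block fit has 1 residual degree of freedom, and no list passed there with an estimated correlation or fry. With an estimated correlation the glycolysis and MYC lists were both at an adjusted p of 0.577. Fry gave them adjusted p-values of 0.22 and 0.137. These misses therefore do not bear on the glycolysis list in particular. The block also called 4 glycolysis genes lower, and 3 genes of the Notch machinery list higher and 2 lower. It called 1 G2 and mitosis gene higher, 1 myeloid marker lower, 1 erythroid marker higher and 1 lower, and no S phase gene. Higher and lower calls were 0 and 12 for cholesterol, 1 and 7 for ER stress, 10 and 1 for T-cell development, and 1 and 12 for Notch targets. An intensity trend gave 663 higher and 636 lower genes, and a robust prior with it 679 and 666. An adjusted p under 0.1 gave 853 and 824, and at least 1.5-fold gave 310 and 223. All probe sets gave 580 higher and 283 lower, 67.2% higher against 52.3% in the gene fit. Leaving out each array gave 9 to 125 higher and 12 to 66 lower genes, fits with 1 residual degree of freedom that assume the lone array varies like the other group; the cause beyond this was not tested. Camera called 7 lists higher and 4 lower, 5 to 6 and 3 to 5 with an array left out, and 0 and 0 with an estimated correlation, where the Notch list had an adjusted p of 0.287 and the MYC list 0.182; leaving out an array gave 6.05e-06 to 0.000115 for the Notch list and 5.23e-16 to 4.47e-14 for the MYC list. A simulated shifted list also missed the threshold there, at 0.0729. The estimated correlation was 0.0096 for the Notch list and -0.019 for the MYC list, so neither exceeded the preset 0.01. It was far above the preset for the cholesterol (0.552), G2 and mitosis (0.657) and glycolysis lists (0.894). Among the named genes, directions turned for 3 that were not called, the only ones in these fits: Fcer1g (0.034 with quantile normalization, -0.19 to 0.15 with an array left out), Prf1 (-0.30 to 0.14 with an array left out) and Csf1r (-0.079 as the mean of its probe sets). Of 105 named genes, 103 kept their direction and side of the threshold under quantile normalization and 105 under median centring. Among the 63 called ones, 22 lost the call in every fit that left out an array, Myc included (adjusted p 0.0591 to 0.167). Only 6% of simulated changes of 0.5 on the log2 scale were recovered. Fewer genes were changed there than the 865 called in the data, so this share need not hold for the data. Some genes that were not called may have changed by that much, as the limma 95% interval of Mfng (-0.85 to -0.21) allows. For others the interval excludes it, as for Maml1 (-0.06 to 0.47). Without _x_at and _s_at probe sets, chosen after seeing the data, 415 genes were higher and 355 lower, and the ER stress list lost its call (adjusted p = 0.054).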

Other observations

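The tests and genes of this part were chosen after the results were seen. Changed genes lay side by side among the tested genes in the gene order of assembly GRCm38.p6. The longest run held 6 neighbouring tested genes that were all higher with 4OHT: Sacm1l (0.62), Slc6a20a (3.81), Lztfl1 (2.03), Ccr9 (2.41), Fyco1 (0.85) and Cxcr6 (2.38, all log2 changes). A second run of 5 held Sgip1 (0.93), Tctex1d1 (1.53), Wdr78 (1.51), Mier1 (0.81) and Slc35d1 (0.93). Among lower genes, Mpzl2 (-1.63), Mpzl3 (-0.70) and the sodium channel subunit genes Scn2b (-1.37) and Scn4b (-2.33) formed a run. Another held Ddx54 (-0.63), Rasal1 (-1.30) and Dtx1 (-3.41). Il2ra (-2.11) lay between Rbm17 (-0.85) and the interleukin receptor gene Il15ra (-1.54). Exoc3l4 (-3.84) and the predicted gene Gm266 (-3.81) flanked Tnfaip2 (-1.37). In all, 13 runs of 3 or more called genes were found, 6 higher and 7 lower.

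Over the 11564 genes with a place, 92 neighbouring pairs were called in the same direction and 20 in opposite directions. Chance order is argued against, since 10000 shuffles of the calls gave a median of 32 and at most 54. Cross-hybridisation between related neighbours is argued against as the whole cause, since 84 pairs remained after leaving out those whose symbols share their first 3 letters, against at most 53 in shuffles. Transcripts that run on into the next gene stay open. Pairs 2 places apart numbered 42 in the same direction and 26 in opposite directions, within the shuffled same-direction numbers (median 32, highest 53). An excess beyond every shuffle was thus found for immediate neighbours, but a smaller excess 2 places apart is not excluded. A hypothesis that neighbours may share regulatory elements was not tested.

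Because every sample held the construct, an effect of 4OHT itself on the higher genes cannot be excluded by the design. A block of sterol synthesis by 4OHT could raise the genes of that pathway. No rise was found: the cholesterol list had a median log2 change of -0.434, with 19 of 20 members below 0, 6 called lower and 0 higher. The fall did not pass with an estimated correlation (adjusted p = 0.566) or fry (adjusted p = 0.138), which were required only after the values were seen. The explanation stays open because, with the construct in every sample, a rise from 4OHT could be hidden by a fall from the construct. An effect through the oestrogen receptor cannot be told apart from the construct's effect, since every sample held the construct. Neither a pass nor a miss of the target list could separate them. The list missed the threshold (camera adjusted p = 0.1382, which was 0.0173 with a filter at the 60th percentile), while Greb1, Esr1 and Ctsd rose. With an array left out, the log2 change ranged from 0.58 to 0.84 for Esr1, 0.44 to 0.48 for Ctsd and 0.68 to 0.94 for Greb1. These genes lost calls in such fits, as most of the called named genes did, so the loss does not set them apart.

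Replicate 2 differed from replicate 1 in both groups. In a limma fit with the replicate number as a term, 105 genes were higher and 45 lower in replicate 2. Jun was higher by 2.98 in ethanol and 2.55 in 4OHT on the log2 scale (adjusted p = 2.41e-05), Fos by 2.62 and 2.14 (adjusted p = 6.73e-05) and Egr1 by 1.74 and 1.07 (adjusted p = 0.00409); all are immediate early genes. The Notch-responsive gene Hey1 was higher by 1.06 and 1.23 (adjusted p = 0.00197). Its difference of -0.67 between 4OHT and ethanol did not pass (adjusted p = 0.452) in the fit without the replicate term. The spread in that fit contains the replicate difference, so the 2 p-values cannot be set against each other. The collagen-modifying enzyme genes P4ha2 (1.47 and 1.06) and Plod2 (0.80 and 0.80) were also higher, and the glycolysis list had a median of 0.38 (camera adjusted p = 1.43e-13). Camera also placed the ER stress (median 0.23, adjusted p = 5.00e-04), cholesterol (0.14, adjusted p = 0.00584) and G2 and mitosis lists (0.13, adjusted p = 0.0165) higher in replicate 2, and the interferon list lower (-0.18, adjusted p = 0.00584). None of these 5 passed with an estimated correlation (adjusted p = 0.775 for each). No list reached a lower value in that test, whatever its camera p. With 1 residual degree of freedom in this fit, it could not decide between them. The G2 and mitosis median was 0.14 between 4OHT and ethanol. The histone gene H3c4 differed by -1.29 and -1.57 (adjusted p = 0.00101).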
